A study of Arabidopsis thaliana with 4 samples.

How the data were processed

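Single-nucleus RNA sequencing was carried out on inflorescences of Arabidopsis thaliana plants (Landsberg erecta) mutant for AP1 and CAL (alleles ap1-1 and cal-1) that carried a dexamethasone-inducible AP1-GR fusion driven by the AP1 promoter. Per the labels' protocols, bolted plants were treated every day with 2 µM dexamethasone and 0.016% of the surfactant Silwet L-77, and inflorescences were taken before treatment and 2, 4 and 8 days after it began, about 20 per sample. The uninduced plants are labelled as not induced, and no library of plants sprayed without dexamethasone was analysed here. Nuclei were isolated from frozen tissue, sorted on DAPI stain, dispensed on a nanowell chip (SMARTer ICELL8) and chosen well by well from images, per the labels' protocols. Each of the 4 libraries is 1 chip and 1 day, so the comparisons are between single libraries.

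The authors deposited, for each library, a matrix of read counts per gene and well and a list of the chosen wells with the image software's stain signal. The counts are whole numbers that are often large for a gene in a nucleus, and no collapse of duplicate molecules is visible in the values, so the deposited counts were taken as reads and not as molecules. Alignment with STAR 2.7.2a to TAIR10 is named in the submitters' processing notes, and the counting tool and annotation release are not given in the sources used here. The deposited stain signal is the value of the image software per well, per the file headers, and was compared only within a chip. It was empty for wells in which the software found no nucleus. All matrix columns were found in the well lists.

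Each matrix listed 32833 genes, of which 32548 were nuclear-encoded and 285 were chloroplast or mitochondrial. All 32548 nuclear identifiers were paired with symbols through a table of the assembly TAIR10.1, which was used for names only, and no coordinates were taken from it. Organelle genes took 4.93%, 7.41%, 4.61% and 4.09% of reads on day 0, 2, 4 and 8 and were left out of the totals. Of 267 genes in the gene and marker lists, all were in the matrix; A6 was dropped from the tapetum list because the table gives its locus another symbol, MEE48, and does not list A6 among the synonyms.

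Reads were summed over the nuclei of each library and divided by the library's nuclear-encoded total to give CPM, with exact Poisson 95% intervals. Ratios between libraries have exact conditional binomial 95% intervals, and shares of nuclei have exact Clopper-Pearson 95% intervals; ratios of shares have normal 95% intervals on the log scale. A ratio against 0 reads was computed against a floor of 3 reads and is given as a lower bound; none is given where both libraries had 3 reads or fewer. No test across genes was possible with 1 library per day, so no p-value is given. Genes were listed by size: at least 2-fold with at least 20 reads in the higher library. The median log2 fold of all genes with enough reads was 0.09, 0.14 and 0.15 on day 2, 4 and 8, against -0.03, -0.04 and -0.02 with TMM factors, and the ratios should be read relative to that shift. The clustering and count steps had been planned for molecule counts, and the planned steps were kept. A count of nuclei with at least 3 reads per gene was added after seeing the data as a measure that deep nuclei cannot dominate. In it, a gene's number of such nuclei took the place of its reads. It was divided by the library's sum of these numbers over all genes. Ratios by this measure are therefore not ratios of shares of nuclei. The minimum of 20 then applied to nuclei and not to reads, so sparse members of a list can drop out.

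The 9 gene lists and 14 marker lists, the size rule and the rule for named genes were written before the data were examined. A list's value is the median log2 fold of its members with at least 20 reads in the libraries compared, on counts plus 0.5, and its percentile is its place among 10000 random lists of the same size drawn within 100 expression ranks to each side of each member. The rule named, per comparison, the 27 floral identity regulators and then the 8 highest and 8 lowest genes by the interval bound nearest 1 among genes with at least 50 reads, of which the first 3 fall within a limit of 30 genes. Members named from the other lists go beyond that limit and are a selection, made after their values were seen, from the rule's up to 2 higher and 2 lower members with a ratio of at least 1.5. Other genes named, and days given for comparison of a gene named elsewhere, were chosen after their values were seen.

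For clusters, nuclei with at least 500 reads and 200 genes were kept (1030, 1319, 741 and 1052). Seurat 5.3.0 was run with log-normalisation, 2000 variable genes, CCA integration over the libraries, 30 components and Louvain clustering at resolution 0.8 with seed 1. Since chip and day are the same variable, integration can remove part of a real difference between days. A cluster was named when the median of a marker list was at least 1.5-fold that of other nuclei, with at least 3 markers at 1.5-fold; it stayed unnamed where more markers of another list were among its 10 leading genes, or where none of its own were and its median depth was below that of the libraries divided by 3. These thresholds were set after the clusters had been seen. Doublets were judged only from the well lists, which counted more than 1 nucleus in 2, 2, 0 and 2 wells, and no doublet caller was run. The image software found no nucleus in 72.7%, 67.1%, 52.2% and 80.4% of the selected wells, so doublets could not be judged in those. Shares of nuclei with at least 3 reads are from unthinned nuclei and depend on depth unless thinning is stated; for thinned shares, nuclei were thinned to 20000 reads, which left out 231, 38, 1 and 304 shallower nuclei.

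The fold, interval and list steps were tested on simulated Poisson counts per library, with 200 changed genes per comparison. The simulation held no single nuclei and no amplification. Its results check the calculation and do not show how well the intervals cover for the real reads. All 50 genes of each size (3-fold and 6-fold, higher and lower) were recovered in each of the simulated day 2, 4 and 8 comparisons, 38, 37 and 56 of 32328 unchanged genes passed the size rule, and 95.5%, 95.4% and 95.4% of intervals held the true fold. A planted list of 20 genes at 1.5-fold gave medians of 0.59, 0.57 and 0.59 on the log2 scale, each at percentile 100.

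Alternatives tried were TMM factors (edgeR 4.0.16), median-of-ratios factors (DESeq2 1.42.0), equal weight per nucleus, equal class weights, other totals, count minima and pseudocounts, other selections of nuclei, thinning, and other cluster settings. Overlaps of the gene lists between days were not reported because the comparisons share the day 0 library. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.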

Results

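The series holds 4 single-nucleus RNA sequencing libraries from inflorescences of Arabidopsis thaliana plants (accession Landsberg erecta) in which flower formation can be switched on. The plants were mutant for APETALA1 (AP1) and CAULIFLOWER (CAL), related MADS-domain transcription factors that give meristems floral identity, and carried AP1 fused to the hormone-binding domain of the glucocorticoid receptor under the AP1 promoter. In such plants meristems keep producing further meristems in place of flowers, and dexamethasone allows the fusion protein to act in the nucleus. The libraries came from uninduced inflorescences (day 0) and from inflorescences harvested 2, 4 and 8 days after the start of daily dexamethasone treatment, with 1 library per day. The time course asks how the transcriptome of floral tissue changes over the early stages of flower development.

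The day 0, 2, 4 and 8 libraries held 1036, 1320, 741 and 1071 nuclei, with 200378090, 141005563, 165144500 and 148100890 reads in nuclear-encoded genes. A nucleus had a median of 69535.5 reads on day 0, 81763 on day 2, 181105 on day 4 and 46230 on day 8, and a median of 3449, 4037, 6009 and 2673 detected genes. Reads were unevenly spread over nuclei: the 5% of nuclei with the most reads held 33.9%, 20.19%, 15.1% and 48.7% of the reads on day 0, 2, 4 and 8. Because each day is a single library on its own chip, no difference below has a replicate check, and day and chip cannot be told apart. The 95% intervals cover only the counting error that independent reads would have. Amplified reads without molecular identifiers are not independent molecules, so the intervals are too narrow.

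AP1 transcripts were present before induction and higher at every later day. Reads summed over nuclei and scaled to the library's nuclear-encoded total gave 173 CPM on day 0, 486 on day 2, 350 on day 4 and 232 on day 8, which is 2.80-fold (95% interval 2.76 to 2.84), 2.02-fold (1.99 to 2.04) and 1.33-fold (1.31 to 1.35) the day 0 level. The share of nuclei with at least 3 AP1 reads was 49.8% on day 0, 83.6% on day 2, 86.4% on day 4 and 35.7% on day 8, and 39.8%, 70.2%, 63.1% and 32.7% in nuclei thinned to 20000 reads. With every nucleus given the same weight the day 8 ratio was 0.971, so the day 8 excess rested on deep nuclei. These reads can come from the transgene, the mutant allele or both.

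**Figure D1:**
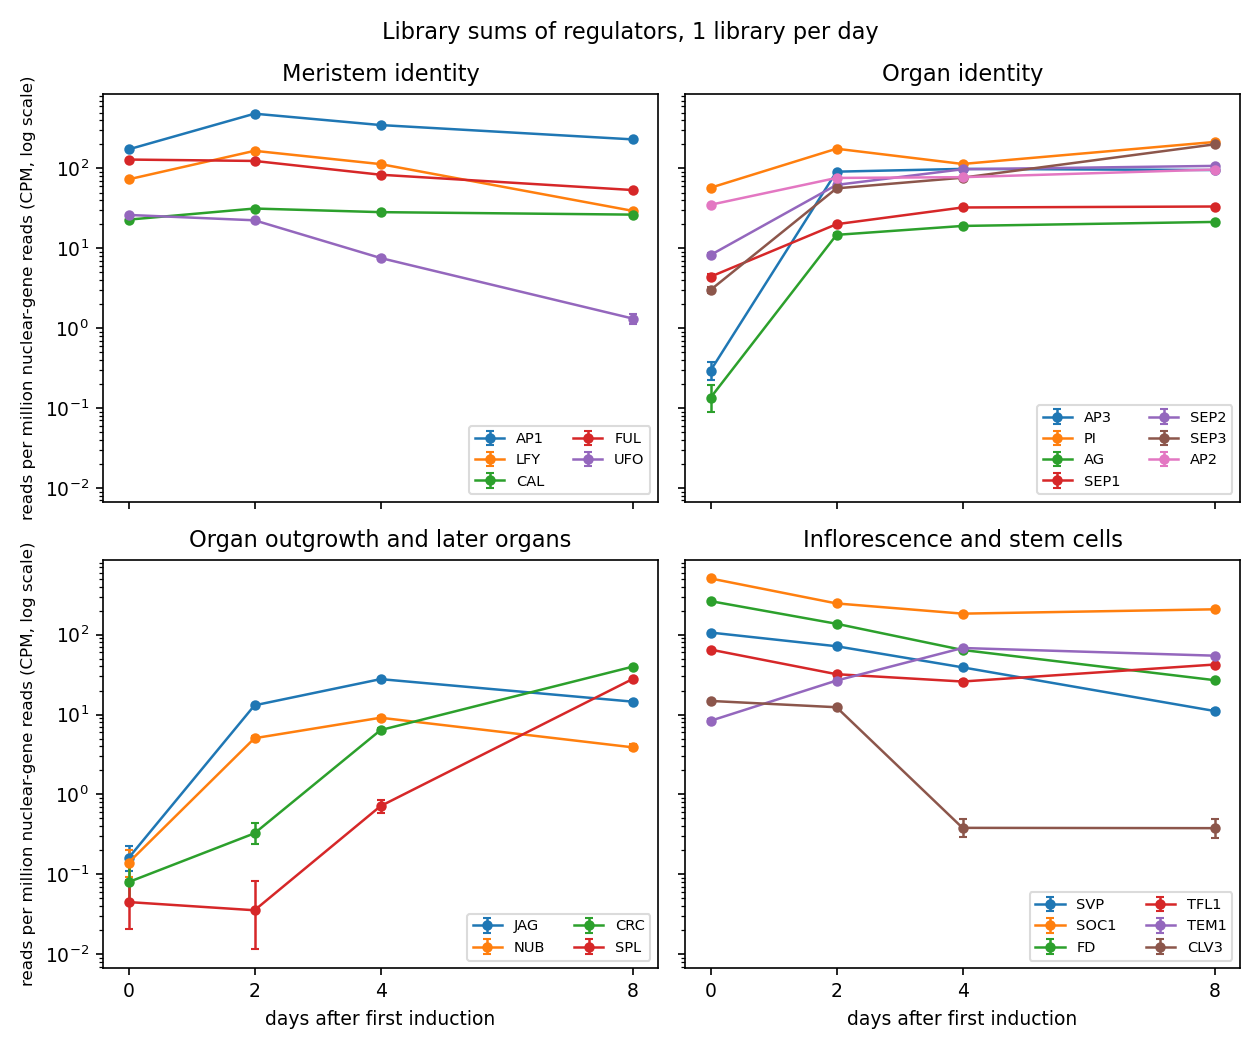
Expression of floral and inflorescence regulators by day, as CPM of reads summed over the nuclei of each library (log scale, 1 library per day, bars show the exact Poisson 95% interval), in panels for meristem identity, organ identity, organ growth and patterning, and inflorescence and meristem genes. AP3 stood at 0.294 CPM on day 0 and at 91.3, 98.8 and 95.7 CPM on day 2, 4 and 8, while SVP went from 106 CPM on day 0 to 11.1 CPM on day 8.

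Day 2 was compared with day 0 to see what differed soon after AP1 was activated. The B-class gene AP3, which specifies petals and stamens, was 310-fold higher (95% interval 240 to 407), at 91.3 against 0.294 CPM, and 36.7% of nuclei had at least 3 AP3 reads against 0.29% on day 0 (22.9% and 0.12% in nuclei thinned to 20000 reads). The C-class gene AG, which specifies stamens and carpels, was 110-fold higher (75.1 to 167), and the E-class genes SEP3, SEP2 and SEP1, which act with the other floral MADS-domain factors, were 18.7-fold, 7.55-fold and 4.55-fold higher. PI, the partner of AP3, was already at 57.4 CPM on day 0 and was 3.08-fold higher (3.01 to 3.15). JAG and NUB, zinc finger regulators of organ growth, were 81.7-fold and 36.2-fold higher, although a single nucleus held 84.4% of the day 0 JAG reads and 67.9% of the day 0 NUB reads. LFY, which activates floral homeotic genes, was 2.28-fold higher (2.23 to 2.32) and AP2 2.17-fold (2.1 to 2.23).

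Of 24 measured flower meristem and floral organ identity regulators, 14 were at least 2-fold higher on day 2 and 0 were at least 2-fold lower. The list's median log2 fold was 1.34, above all 10000 random lists of the same size and expression level, and 0.62 in counts of nuclei with at least 3 reads. Beyond the genes above, the 14 were completed by CRC, a carpel and nectary regulator (4.09-fold, 2.27 to 7.73), SUP (3 reads on day 0, ratio 32.7, interval 10.7 to 162) and RBE, a petal regulator (1 read on day 0, ratio 321, interval 57.1 to 12741). Smaller ratios were 1.38 for CAL, 1.37 for SEP4, 1.17 for SPT, 1.13 for PTL, 1.08 for MYB17, 0.961 for FUL, 0.857 for UFO, 0.743 for SHP1, 0.668 for AGL6 and 0.522 for LMI1. STK, SHP2 and SPL had 10, 4 and 5 reads on day 2 and were too sparse to rank.

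By the lower bound of the interval, the 3 highest genes on day 2 were not floral regulators, and AP3 came next. AT5G09570, which codes for a small protein of the CHCH domain family, had 2 reads on day 0 and 5456 on day 2, a ratio of 3877 (1073 to 32019). AT5G24640 had 0 reads on day 0 and was at least 658-fold higher, and AT5G51440, which codes for a small heat shock protein, was 715-fold higher (376 to 1564). All 8 of the genes with the largest day 2 deficit by the same ranking had most of their day 0 reads in a single nucleus.

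Inflorescence and flowering-time regulators were lower as a group on day 2. Their median log2 fold was -0.57, below all 10000 random lists, with 5 of 19 members at least 2-fold lower and 2 at least 2-fold higher. TFL1, which keeps the shoot apex indeterminate, was 2.03-fold lower (1.97 to 2.1) and the AP2-like repressor TOE3 2.65-fold lower (2.47 to 2.85), whereas the floral repressor TEM1 was 3.19-fold higher (3.01 to 3.38). Shoot meristem and boundary regulators had a median of 0.01 on the log2 scale, with WUS, which maintains the stem cell niche, 2.63-fold higher (2.40 to 2.89) and the boundary gene LOB 2.2-fold lower (2.02 to 2.39).

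Organ primordium, growth and polarity regulators had a median log2 fold of 0.37 on day 2 (percentile 99.3 of random lists), with DRNL, an early primordium gene, 2.77-fold higher (2.60 to 2.95). The auxin list had a median of 0.14 (percentile 62.1), with the auxin-conjugating enzyme genes GH3.3 and GH3.5 at 3.40-fold and 2.03-fold. The gibberellin list had a median of 0.42 (percentile 93.9), with GA20OX1, a biosynthesis gene, 2.04-fold lower and the DELLA repressor gene RGL2 4.28-fold higher. The gynoecium and ovule list had a median of -0.41 (percentile 1.76), with STY1 3.09-fold and BEL1 2.58-fold lower, but its median was 0.15 without the 5% deepest nuclei. Genes of heat, wounding and touch had a median of 0.21 (percentile 67.5) and clock genes 0.30 (percentile 91.7), with ERF5 2.60-fold higher, TCH2 1.65-fold lower and ELF3 1.79-fold higher.

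Among the marker lists on day 2, photosynthetic genes stood lowest against their random lists. Their median log2 fold was -0.53, below all random lists, with the Rubisco small subunit genes RBCS1B and RBCS3B 2.86-fold and 2.27-fold lower; these near-identical copies may share reads. Median log2 folds were -0.15 for epidermis, -0.69 for the guard cell lineage, -0.80 for xylem, -0.25 for phloem and 0.29 for procambium. They were -0.25 for S phase, 0.30 for G2/M phase, 0.02 for shoot meristem, -0.21 for organ boundary and 0.37 for the abaxial domain. Examples were the cell cycle genes CDC20.1 and CDC20.2 at 1.91-fold and 1.98-fold, the xylem protease genes XCP1 and XCP2 at 5.44-fold and 3.26-fold lower, and the stomatal peptide gene EPF2 at 2.62-fold lower. The B-function list stood at 4.82 (0.86 in counts of nuclei with at least 3 reads). The 4.82 is the value of SUP alone, which had few day 0 reads. Sparse members of a list can drop out of counts of nuclei. The C-function list stood at 1.12 and the sporogenous and tapetum list at -0.01, with the anther receptor gene EMS1 2.28-fold higher and the meiotic recombinase gene DMC1 2.76-fold lower.

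By size alone, 2541 genes were at least 2-fold higher and 1877 at least 2-fold lower on day 2, with at least 20 reads in the higher library. With each gene counted as nuclei with at least 3 reads, scaled to the library's sum over genes, 299 and 259 passed. Of these, 267 and 144 were among the former. With TMM factors 2282 were higher and 2158 lower.

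Day 4 was compared with day 0 in the same way. AP3 was 336-fold higher (260 to 441), AG 142-fold (97.2 to 215), SEP3 25.4-fold (23.4 to 27.7), SEP2 11.8-fold (11.3 to 12.5) and SEP1 7.36-fold (6.85 to 7.91). JAG stood at 174-fold (123 to 255), NUB at 65.3-fold (45.0 to 98.6) and CRC at 80.0-fold (49.0 to 140). UFO, an F-box partner of LFY in B-gene activation, was 3.46-fold lower (3.25 to 3.68). Of the 25 measured floral identity regulators 13 were at least 2-fold higher and 1, UFO, at least 2-fold lower. The median log2 fold was 1.01, above all random lists. In counts of nuclei with at least 3 reads it was 0.437. The random lists of reads, whose upper bound was 0.439, are not matched to that measure and do not place it.

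AP2 was 2.22-fold higher on day 4, SUP had a ratio of 80.5 (27.1 to 394) over 3 day 0 reads and RBE 724 (130 to 28658) over 1 day 0 read. SPL, a sporogenesis regulator, had a ratio of 15.9 (8.10 to 35.6), with 91.5% of its day 4 reads in a single nucleus. The remaining ratios were 1.99 for PI, 1.55 for LFY, 1.40 for SHP1, 1.36 for PTL, 1.24 for CAL, 1.14 for SEP4, 1.05 for LMI1, 0.831 for AGL6, 0.787 for MYB17, 0.646 for FUL and 0.538 for SPT. STK had 9 reads and SHP2 had 2. At the top of all genes were AT5G09570 (ratio 4336, 1200 to 35810), the transporter gene AT2G04050 (1419, 793 to 2842) and AT5G24640 (at least 683-fold). At the other end the phosphate transporter gene PHT1;4 was 408-fold lower (207 to 945), at 0.048 against 19.8 CPM, while 4 of the 8 lowest genes had most of their day 0 reads in a single nucleus.

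Shoot meristem and inflorescence regulators were lower as groups on day 4. The shoot meristem and boundary list had a median log2 fold of -0.77 and the inflorescence list -1.01, both below all random lists, with 6 of 16 and 10 of 19 members at least 2-fold lower. CLV3, the stem cell peptide gene, was 38.8-fold lower (30.3 to 50.7), BOP1 5.94-fold (5.13 to 6.90) and CUC2, a boundary gene, 2.51-fold lower (2.39 to 2.64). TFL1 was 2.51-fold lower (2.43 to 2.60), TEM1 was 8.16-fold higher (7.75 to 8.59) and the receptor kinase gene ER 1.79-fold higher (1.77 to 1.81). Genes of heat, wounding and touch stood higher in the same library, with a median of 0.99 (percentile 99.8) and 7 of 15 members at least 2-fold higher, among them ZAT12 at 9.56-fold.

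Some polarity genes were higher on day 4. The abaxial genes YAB3 and FIL were 4.18-fold (4.07 to 4.29) and 2.95-fold (2.90 to 3.00) higher and PHV, an adaxial HD-ZIP gene, 2.98-fold (2.91 to 3.06), whereas the primordium genes PUCHI and DRN were 5.48-fold and 5.05-fold lower. The organ primordium list had a median log2 fold of 0.50 (percentile 99.0) with 7 of 20 members at least 2-fold higher and 3 lower, and 0.12 in counts of nuclei with at least 3 reads. The auxin list had a median of -0.21 (percentile 4.89), with IAA29 41.5-fold and IAA20 15.1-fold lower, and GH3.3 and GH3.5 3.51-fold and 2.88-fold higher. The gibberellin list had a median of 0.53 (percentile 90.8), with the receptor gene GID1B 4.73-fold higher and GA20OX1 2.88-fold lower. The gynoecium list had a median of 0.08 (percentile 31.8), with NGA1 68.2-fold higher and BEL1 7.33-fold lower, and the clock list 0.77 (percentile 99.6), with ELF3 2.19-fold higher.

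DNA replication genes were lower on day 4. The S-phase list had a median log2 fold of -0.67, below all random lists, with the histone H4 gene AT3G53730 3.05-fold lower (948 against 311 CPM) and PCNA1, the replication clamp, 2.89-fold lower; reads of histone genes may be shared between copies. The G2/M list had a median of 0.20, with CDC20.1 and CDC20.2 at 2.60-fold and 2.7-fold higher. Medians were 0.14 for epidermis, -0.30 for xylem, 0.53 for phloem, 0.37 for procambium, -0.77 for shoot meristem, -0.71 for organ boundary and 1.07 for the abaxial domain (0.53 in counts of nuclei). They were 6.11 for B function (0.43 in counts of nuclei with at least 3 reads), 3.04 for C function and -0.03 for the sporogenous and tapetum list. The 6.11 is the value of SUP alone, which had few day 0 reads. In counts of nuclei sparse members of a list can drop out. Named members were LTP1 and CER1, lipid transfer and wax genes of the epidermis, at 1.55-fold and 1.84-fold, the sieve element genes SEOR1 and SEOR2 at 3.14-fold and 3.38-fold, and ATHB8 at 1.79-fold. The guard cell list had a median of -1.06 and the photosynthetic list 0.32, and in counts of nuclei with at least 3 reads these were 0.34 and -0.14; FAMA, a guard cell regulator, was 4.83-fold lower, and LHCA4 and LHCB4.1, light-harvesting genes, were 1.99-fold and 1.76-fold higher.

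By size, 3807 genes were at least 2-fold higher and 2276 at least 2-fold lower on day 4 than on day 0. Counted by nuclei with at least 3 reads the numbers were 962 and 397, of which 816 and 302 were among the former. With TMM factors 3158 were higher and 2835 lower. Higher genes made up 62.6% of the listed genes by reads, 52.7% with TMM factors and 70.8% in counts of nuclei. The size of their excess thus depended on the scaling and the measure.

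Day 8 was compared with day 0 as the latest point of the series. Genes of the tapetum, the layer that nourishes pollen, and of anther development were near 0 on day 0 and abundant on day 8. AMS, a tapetum transcription factor, stood at 480 against 0.454 CPM (1057-fold, 861 to 1313), A9 at 484 against 0.434 CPM (1114-fold, 903 to 1391), and SPL, which starts sporogenesis, at 27.8 against 0.045 CPM (620-fold, 326 to 1356). The sporogenous and tapetum list had a median log2 fold of 7.96, above all random lists, with 10 of 15 measured members at least 2-fold higher and 0 lower. The highest genes by the lower bound of the interval were AT5G44540 (2629, 1930 to 3680), AT3G07450 (2203, 1598 to 3130) and AT5G62080 (1443, 1275 to 1641), the last at 1793 CPM. The meiotic genes SDS and DMC1 were 1.61-fold and 1.64-fold lower. Reads of A9 were found in most nuclei of the library. At least 3 were present in 66.8% of day 8 nuclei, and in 61.4% after each nucleus was thinned to 20000 reads. Of 46 negative control wells 3 had at least 3. Such a well had a median of 646 reads against 46230 in a nucleus, so these shares are not at like depth. In a cluster led by AMS that formed only without integration the thinned share was 88.9% of 63 nuclei, against 58.9% of 704 other day 8 nuclei. Free RNA was not removed and can contribute to the wide spread.

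Several floral organ identity genes were again far above their day 0 level on day 8. SEP3 was 66.6-fold higher (61.4 to 72.3), AP3 325-fold (252 to 427), AG 159-fold (109 to 242), CRC 497-fold (306 to 871), PI 3.74-fold (3.66 to 3.82), SEP2 13.1-fold and SEP1 7.57-fold. The meristem identity genes LFY, FUL and UFO were 2.48-fold (2.39 to 2.56), 2.41-fold (2.35 to 2.47) and 19.8-fold (17.2 to 23.0) lower. Of 25 measured members 15 were at least 2-fold higher and 4 at least 2-fold lower, the fourth being MYB17 at 2.19-fold, and the median log2 fold of 1.90 lay above all random lists. In counts of nuclei with at least 3 reads the median was 0.25. The random lists of reads, whose upper bound was 0.489, are not matched to that measure and do not place it. JAG stood at 90.9-fold, NUB at 27.8-fold, STK at 30.9-fold, SHP1 at 4.47-fold, AP2 at 2.76-fold and AGL6 at 2.30-fold higher. SUP had a ratio of 32.9 (10.8 to 163) over 3 day 0 reads. Other ratios were 1.81 for LMI1, 1.16 for CAL, 1.01 for PTL, 0.527 for SPT and 0.511 for SEP4; RBE and SHP2 had 11 and 6 reads.

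Meristem and inflorescence genes were lower again as groups on day 8. The shoot meristem and boundary list had a median log2 fold of -1.56, below all random lists, with 11 of 16 members at least 2-fold lower (-0.743 in nuclei of 20000 to 200000 reads), and the inflorescence list -0.71 (percentile 0.03) with 6 of 19. FD, a flowering-time bZIP factor of the shoot apex, was 9.77-fold lower (9.46 to 10.1) and SVP, a MADS-domain repressor of flowering, 9.60-fold (9.13 to 10.1). CLV3 was 39.2-fold, BOP1 17.4-fold, CUC1 3.45-fold and CLV1 3.40-fold lower, and TEM1 was 6.54-fold higher. Among the lowest of all genes were PUM10 (754-fold lower, 294 to 2770) and WIP5 (277-fold lower, 127 to 755), and 2 of the lowest 8 had most of their day 0 reads in a single nucleus. Heat, wounding and touch genes stood higher in this library, with a median of 2.19, above all random lists, and 12 of 15 members at least 2-fold higher; the cold and drought genes COR15A and RD29A were 34.5-fold (31.6 to 37.7) and 28.5-fold (26.2 to 30.9) higher, and the heat gene HSP101 and TCH2 were 2.55-fold and 2.14-fold lower (with every nucleus given the same weight HSP101 was 1.52-fold higher).

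Hormone and organ lists gave mixed values on day 8. The auxin list had a median log2 fold of -0.55 (percentile 0.45), with IAA29 at 3 reads on day 8 and a ratio of 286 (97.5 to 1387) in favour of day 0, the auxin biosynthesis gene YUC4 20.0-fold lower and GH3.5 and GH3.3 3.49-fold and 2.75-fold higher; without the 5% deepest nuclei the median was 0.0046. The gibberellin list had a median of 1.12 (percentile 97.6), with RGL2 7.96-fold higher. The gynoecium list stood at 1.75 (percentile 99.3), with NGA1 55.9-fold higher and STY1 12.7-fold lower. However, counts of nuclei, where sparse members can drop out, gave -0.30 and -0.97. The organ primordium list had a median of -0.07 (percentile 26.2), with YAB3 3.3-fold higher and DRN and PUCHI 220-fold and 115-fold lower. The clock list had a median of 0.57 (percentile 92.4), with LHY 2.78-fold lower.

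Replication genes were lower as a group on day 8 as well. Of 18 S-phase genes 17 were lower, 9 of them at least 2-fold, and 1, CDC6, was higher. The S-phase median was -1.01, below all random lists, with PCNA1 4.36-fold and the histone H3 gene HTR9 4.34-fold lower, and the G2/M median was -0.31 (percentile 1.53), with CDKB2;1 2.14-fold lower and CDC20.2 and CDC20.1 2.21-fold and 1.98-fold higher. Medians were -0.42 for epidermis, 0.56 for the guard cell lineage, 0.62 for xylem, 0.32 for phloem, 0.25 for procambium and 0.17 for photosynthetic genes, the last being -0.0051 with TMM factors. They were -0.83 for shoot meristem, -1.61 for organ boundary, 3.37 for B function (1.12 in counts of nuclei), 4.98 for C function and 0.31 for the abaxial domain. The 3.37 lies midway between PI and SUP, and SUP had few day 0 reads. Counts of nuclei can lack sparse members of a list. In the epidermis list CER1 was 2.05-fold higher and PDF1 and PDF2 1.78-fold and 1.74-fold lower. SEOR2 was 3.24-fold and SEOR1 1.63-fold higher, FTIP1 5.91-fold and FAMA 3.32-fold lower, ATHB8 1.69-fold higher, and the auxin response factor gene MP 2.27-fold lower. IRX1, a cellulose synthase gene, had a ratio of 5.27 with 70.9% of its day 8 reads in a single nucleus, and 0.927 in counts of nuclei.

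By size, 5279 genes were at least 2-fold higher and 2968 at least 2-fold lower on day 8 than on day 0. Counted by nuclei with at least 3 reads the numbers were 1295 and 954, of which 1177 and 646 were among the former. With TMM factors 4648 were higher and 3581 lower.

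**Figure D2:**
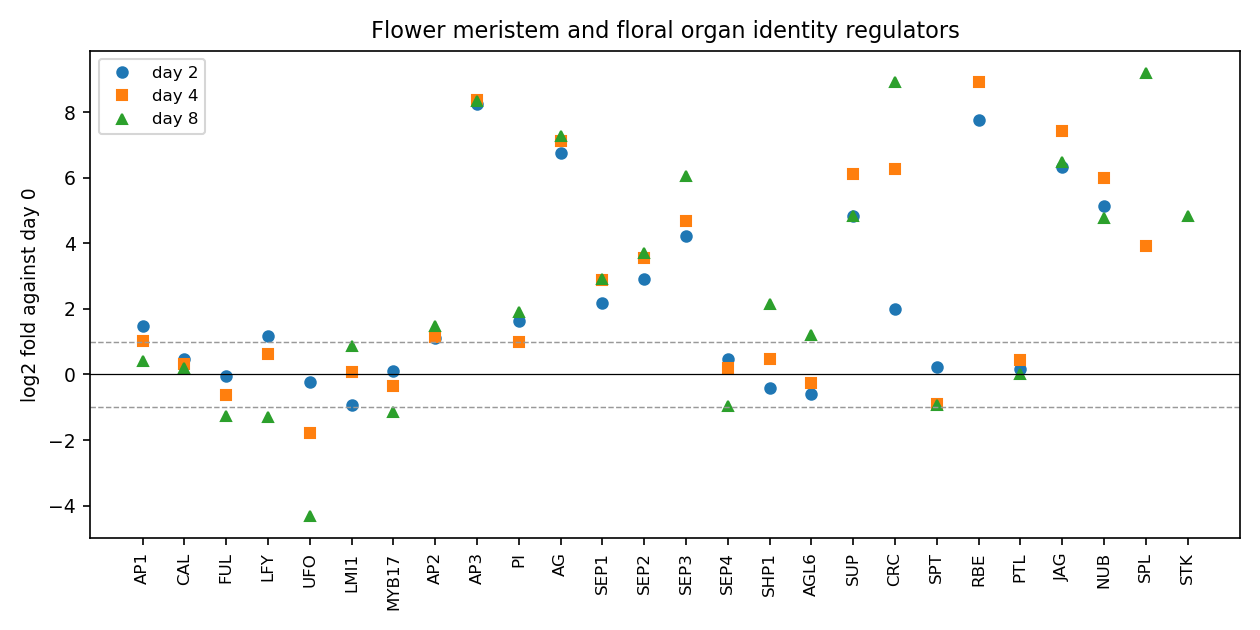
Log2 fold against day 0 of flower meristem and floral organ identity regulators on day 2, 4 and 8 (1 library per day; dashed lines mark 2-fold; values from fewer than 20 reads in both libraries together are left out). AP3, AG, SEP3, JAG and NUB lay above 2-fold on all 3 days, and UFO went from 26.2 CPM on day 0 to 1.32 CPM on day 8.

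Between successive days, 2649 genes were at least 2-fold higher on day 4 than on day 2, and 4047 on day 8 than on day 4; by counts of nuclei these were 656 and 830, with 489 and 743 shared. CRC stood at 0.326 CPM on day 2, 6.39 on day 4 and 39.7 on day 8, and SPL at 0.035, 0.715 and 27.8. SEP3 stood at 56.4, 76.7 and 201 CPM, whereas LFY stood at 166, 113 and 29.5. FD stood at 263, 137, 64.4 and 26.9 CPM on day 0, 2, 4 and 8, and SVP at 106, 71.6, 39.0 and 11.1. CLV3 stood at 14.8 and 12.3 CPM on day 0 and 2 and at 0.381 and 0.378 on day 4 and 8.

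**Figure D3:**
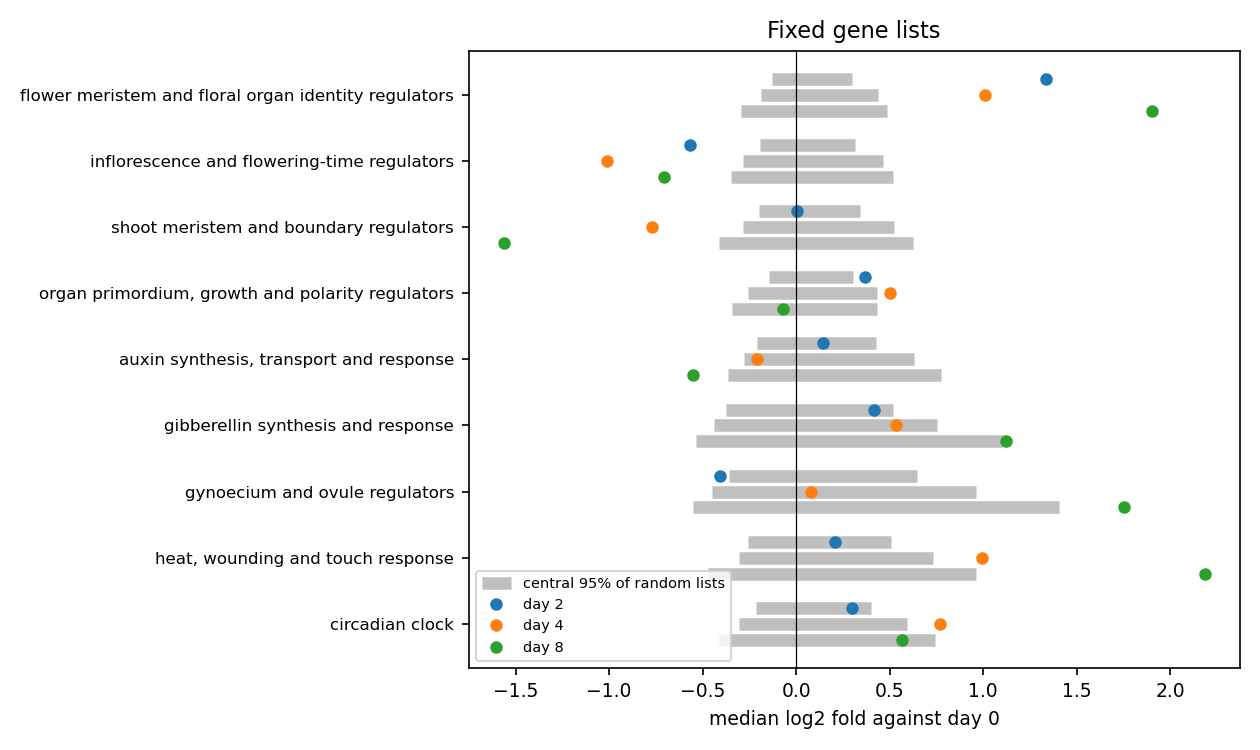
Median log2 fold against day 0 of 9 gene lists on day 2, 4 and 8, with the central 95% of 10000 random lists of the same size and expression in grey. The floral identity list lay at 1.34, 1.01 and 1.90, the shoot meristem and boundary list at 0.01, -0.77 and -1.56, and the heat, wounding and touch list at 0.21, 0.99 and 2.19.

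Nuclei were clustered jointly to ask in which cell types these genes were expressed. Of the 11 clusters, 5 met both requirements for a name, on the median of a marker list and on the number of raised markers: an epidermis-like class, a G2/M-like class, a xylem-like class and a phloem-like class made of a pair of clusters. The unnamed remainder was 85.6%, 81.3%, 78.4% and 83.9% of nuclei on day 0, 2, 4 and 8. The epidermis-like class, led by the wax genes CER4 and CER1, held 4.27% (exact 95% interval 3.12 to 5.69), 4.25% (3.22 to 5.48), 6.07% (4.46 to 8.04) and 7.51% (5.99 to 9.27). The G2/M-like class, led by CDC20.1, CDC20.2 and FZR3, held 6.02% (4.65 to 7.65), 10.3% (8.72 to 12.1), 9.31% (7.32 to 11.6) and 4.47% (3.3 to 5.90). The xylem-like class held 2.43%, 2.12%, 4.05% and 2.85%, and the phloem-like class, with SEOR1, SEOR2 and CALS7 among the leading genes of its smaller cluster, 1.65%, 1.97%, 2.16% and 1.24%. Nuclei were sorted on DNA stain and wells were picked by image, both of which can set these shares, and class genes themselves differed between days, so no direction is drawn.

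The other clusters did not meet the requirements for a name. A cluster led by FAMA and TGG2, genes of stomatal and myrosin cells, reached only 2 markers and held 0.68%, 0.53%, 0.67% and 0.76% of nuclei. A cluster with raised G2/M genes and the meiotic cyclin gene SDS among its leaders held 11.4%, 11.5%, 14.8% and 8.27%. A cluster led by PMZ, ZAT12 and HSP17.6A, genes of stress responses, held 0.30%, 0.81% and 1.05% of nuclei on day 2, 4 and 8 and 0 of 1030 on day 0. A further cluster, of median 38032 reads, held 15.8% of the day 2 nuclei and between 2.83% and 3.79% of the others.

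Within classes, AP3 was near 0 on day 0 and high on day 2 in each of them. It stood at 66.4 CPM (60.6 to 72.5) in epidermis-like, 85.6 (81.5 to 89.9) in G2/M-like, 88.6 in xylem-like, 91.1 in phloem-like and 94.0 (92.2 to 95.8) in unnamed nuclei on day 2, against at most 0.339 on day 0. On day 8 it stood at 77.7, 38.0, 29.9, 13.5 and 112 CPM in the same order, but at least 3 AP3 reads were found in only 4 of 30 xylem-like and 1 of 13 phloem-like nuclei. SEP3 stood at 58.3, 60.8, 64.0, 32.6 and 56.0 CPM on day 2 and 216, 138, 294, 182 and 210 CPM on day 8, the phloem-like value with at least 3 reads in 2 of 13 nuclei. AP1 stood at 526, 511, 418, 509 and 479 CPM on day 2. Free RNA shared among nuclei was not removed and can contribute to the even values of day 2.

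The DNA stain gave a separate readout of the G2/M-like class, since cells in G2 and M phase hold replicated DNA. Among wells with an image signal, the median signal of G2/M-like nuclei divided by that of other nuclei was 1.02 on day 0 (23 against 260 nuclei), 1.11 on day 2 (56 against 376), 0.878 on day 4 (34 against 320) and 1.16 on day 8 (12 against 195). The ratio was 1.02 to 1.16 in 3 libraries and below 1 in the day 4 library. No interval was computed for it, and the stain gave no clear support to the name of the class. No class led by S-phase markers was found.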

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

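The test of named classes over all libraries was set out before its result was seen; its split by library and the test of carried-over reads alone were chosen after the results had been seen.

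The negative control wells of the chips held reads. Their medians were 572 reads on day 0 (48 wells), 328 on day 2 (44 wells), 737.5 on day 4 (48 wells) and 646 on day 8 (46 wells), which is 0.82%, 0.40%, 0.41% and 1.40% of the median nucleus of the same library.

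Selected wells in which the image software found no nucleus held nearly as many reads as wells with an imaged nucleus. They made up 72.7%, 67.1%, 52.2% and 80.4% of the selected wells on day 0, 2, 4 and 8, and their medians were 68481, 75453, 167163 and 43423 reads, which is 0.930, 0.799, 0.833 and 0.851 times the median of imaged wells. A possible explanation is that part of them are empty wells with free RNA or carried-over reads, which would lower their share in a named class. That share was 16.0% of 2864 wells without an imaged nucleus and 20.8% of 1278 imaged wells, a ratio of 0.767, between the bounds of 0.5 and 0.8 set for the test, so empty wells with free RNA and nuclei missed by the software cannot be told apart over all libraries. By library the ratio was 0.925 (95% interval 0.667 to 1.28) on day 0, 0.670 (0.534 to 0.839) on day 2, 1.06 (0.807 to 1.40) on day 4 and 0.675 (0.497 to 0.916) on day 8. The day 4 interval lay above 0.8 only by its bound of 0.807, which argues weakly against empty wells as a large part of them there. On day 2 and 8 the intervals lay wholly below 1, the direction that empty wells would give. The intervals of day 0, 2 and 8 did not settle it. Carried-over reads alone were argued against, since the median of wells without an imaged nucleus was at least 13.3 times the highest negative control well of the same library. Nuclei had been chosen by hand as well as by software, per the labels, and no biological explanation was tested.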

How the results depend on the processing

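The alternatives with nuclei of at least 10000 reads and 1000 genes, with nuclei of 20000 to 200000 reads, and with counts of nuclei with at least 3 reads were chosen after seeing the data. A count was taken as unmoved within 1.5 times, a share within its exact 95% interval, a ratio within its counting interval, and a list median within the spread of its random lists. By these yardsticks 126 of 136 alternative gene counts, 46 of 96 class shares, 646 of 1344 class CPM values, 1961 of 2996 gene ratios and 781 of 828 list medians were unmoved. Of these gene ratios 2954 stayed on their side of 1. They do not cover every gene and alternative, since the reversal of HSP101 on day 8 with equal weight per nucleus is not among them. Depth limits the comparisons, and the spread of reads over nuclei was most uneven on day 0 and 8. Where a value below differs, the cause was not tested, except that fewer genes can reach 20 nuclei than 20 reads and that dropping the minimum admits sparse genes.

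Counting nuclei with at least 3 reads gave 299 higher and 259 lower genes on day 2 (2541 and 1877 by reads), 962 and 397 on day 4 (3807 and 2276), 1295 and 954 on day 8 (5279 and 2968), 656 higher on day 4 than day 2 (2649) and 830 on day 8 than day 4 (4047). Nuclei of 20000 to 200000 reads gave 1929 lower genes on day 8, of which 1164 were among the 2968, and no count minimum gave 4082 higher on day 4 than day 2. Membership changed more than the counts did: with equal weight per nucleus 1670 of the 2541 higher and 1217 of the 1877 lower genes of day 2 were shared, and with nuclei of 20000 to 200000 reads 695 of the 1877 lower. Over all other settings the higher genes ranged from 1987 to 3762, 3158 to 5673 and 4648 to 6612 on day 2, 4 and 8.

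The floral identity median stayed above 0 under every setting but was 0.62, 0.44 and 0.25 on day 2, 4 and 8 in counts of nuclei, against 1.34, 1.01 and 1.90. The B-function median was 0.86, 0.43 and 1.12 in counts of nuclei against 4.82, 6.11 and 3.37, and the organ primordium median on day 4 was 0.12 against 0.50. The B-function values by reads rest wholly or partly on SUP, which had few day 0 reads. Sparse members can drop out of the values in counts of nuclei. The shoot meristem and boundary median on day 8 was -0.743 in nuclei of 20000 to 200000 reads, against -1.56, and nearer 0 as well with equal weight per nucleus and without the deepest 5%. Counts of nuclei also reversed the medians of guard cell (0.34 against -1.06) and photosynthetic genes on day 4 (-0.14 against 0.32) and of gibberellin (-0.30 against 1.12) and gynoecium genes on day 8 (-0.97 against 1.75), and the ratio of IRX1 on day 8 (0.927 against 5.27). Without the deepest 5% of nuclei the gynoecium median on day 2 was 0.15 against -0.41 and the auxin median on day 8 was 0.0046 against -0.55. Nuclei of 20000 to 200000 reads gave a gynoecium median of 0.016 on day 2, a photosynthetic median of -0.0026 on day 8 (0.17 in all nuclei) and an XCP1 ratio of 1.33 on day 4 (0.348 in all nuclei), and TMM factors a photosynthetic median of -0.0051 on day 8.

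Class shares depended on the clustering. The G2/M-like share on day 0, 2, 4 and 8 was 10.2%, 14.9%, 11.7% and 3.14% without integration, 10.5%, 16.1%, 15.1% and 7.13% at resolution 0.4, 10.3%, 16.1%, 14.6% and 6.08% with 15 components, 11.5%, 16.8%, 16.7% and 7.77% with at least 1000 reads, 10.8%, 14.4%, 14.5% and 7.21% without the deepest 5%, and 10.8%, 15.2%, 13.8% and 6.74% with at least 10000 reads and 1000 genes; thinned to 500 reads it was 6.46% on day 8. The phloem-like share was 0.570% on day 8 without integration, 4.08%, 4.62%, 6.48% and 3.80% at resolution 0.4, 5.48%, 5.76%, 8.10% and 4.79% with at least 1000 reads, and 7.56%, 9.26%, 13.1% and 8.91% without the deepest 5%. The epidermis-like share was 12.4%, 13.4%, 18.9% and 15.4% with 15 components, 6.12%, 6.14% and 8.10% on day 0, 2 and 4 at resolution 1.2, and 5.92%, 5.67% and 9.41% on day 0, 2 and 8 without the deepest 5%. No epidermis-like class arose without integration, at resolution 0.4, with at least 1000 reads, with at least 10000 reads and 1000 genes, or after thinning to 500 reads, which left only the G2/M-like class. No cluster was named xylem-like without integration either; a cluster of 72 day 8 nuclei had raised xylem markers but AMS among its leading genes, and another with leading genes of the xylem-like class was named procambium. The xylem-like share was 3.59% on day 0 at resolution 1.2 and 5.13% on day 8 with 15 components.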

Other observations

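The test of a general stress response and the test on the cluster led by AMS were chosen only after the results were seen, and the gene sets in this part were written down after the highest genes had been seen; members not yet seen then are given apart.

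Genes of the mitochondrial stress response stood far above day 0 on all 3 induced days. AOX1A, the alternative oxidase that marks this response, stood at 1.97 CPM on day 0 and 175, 233 and 145 CPM on day 2, 4 and 8, and at least 3 reads were found in 1.06%, 58.6%, 71.1% and 33.5% of nuclei (0.75%, 40.9%, 43.1% and 30.0% after thinning to 20000 reads). NAC13, a transcription factor that drives these genes, stood at 8.32, 144, 116 and 63.6 CPM, and the sulfotransferase gene SOT12 at 1.34, 176, 317 and 253 CPM. Over the 11 members not seen beforehand the median log2 fold was 4.11, 4.41 and 4.00 on day 2, 4 and 8, above all 10000 random lists, with 10 of 11 at least 2-fold higher each day. In counts of nuclei with at least 3 reads, where 10, 10 and 9 of the members could be measured, the medians were 3.06, 2.97 and 2.46.

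Genes of the response to low oxygen were highest on day 4. LBD41, a core gene of that response, stood at 68.7, 107, 364 and 32.3 CPM on day 0, 2, 4 and 8, with at least 3 reads in 91.2% of day 4 nuclei against 29.2% on day 0 (68.6% and 19.5% after thinning to 20000 reads), and the haemoglobin gene HB1 at 3.00, 13.6, 71.8 and 10.6 CPM. Over 12 members not seen beforehand the median log2 fold was 0.49, 1.46 and -0.44 (percentiles 98.2, 100 and 3.31), and in counts of nuclei 0.38, 1.07 and -0.86 over 9 members. When nuclei were clustered without integration, clusters largely followed the library on day 4 and 8. LBD41 and HB1 led a cluster that held 72.3% of day 4 nuclei and at most 2.12% of the others, a cluster with raised sporogenous and tapetum markers held 81.2% of day 8 nuclei and at most 1.08% of the others, and a cluster led by ABCG26, AMS and CYP704B1, genes of pollen wall formation and the tapetum, held 6.84% of day 8 nuclei and 0 of the others.

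The mitochondrial stress genes were weighed against technical sources. A choice of genes after their values were seen would leave unseen members near random lists, but the lowest median of the unseen members, 4.00, lay above the upper bound of 0.76. A general response to heat, wounding or touch was argued against on day 2 for that list as a whole, whose median of 0.21 lay inside its random lists, beside 4.11. Still, 4 of its 15 members were at least 2-fold higher on day 2 and 0 at least 2-fold lower, so a response of part of the list is not excluded. The general response stays open on day 4, where the list stood at 0.99 beside 4.41. On day 8 it may account for part of the pattern, since the list stood at 2.19, above 0.5 times 4.00, although not all of its members were higher. The daily spray of dexamethasone and surfactant apart from the action of AP1 cannot be told apart from AP1 activity, because 0 libraries were sprayed without dexamethasone. Handling of single chips and an effect of flower development itself remain possible explanations and were not tested.

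The 8 anther and tapetum genes on day 8, among them A9, AMS, LAP5, MEE48 and AT5G62080, were mostly found in many nuclei of every class; the exception was ATA7, found in 7.66% of day 8 nuclei. The median ratio of reads per negative control well to reads per nucleus was 0.0032. Carry-over between wells at the level of the control wells would thus supply few of these reads. Those wells held few reads of any gene, at a median of 1.40% of the median day 8 nucleus. A low ratio was therefore set by their depth and is not particular to these genes. Free RNA shared alike by all nuclei, released when the tissue was broken, may account for the spread over classes, since the highest share divided by the lowest among epidermis-like, G2/M-like, vascular-like and unnamed nuclei had a median of 1.27, under the bound of 1.5, with ATA7, which was found in 0 of 39 G2/M-like nuclei, counted as the most uneven gene. The unnamed group is a mixture, and the classes came from integrated clusters. In the cluster led by AMS without integration the mean thinned reads were higher than in other day 8 nuclei, with a median ratio of 2.27 over the 8 genes, between the bounds of 1.5 and 3, so free RNA and expression in those nuclei cannot be told apart there; AMS itself helped to form that cluster. Cells of the tapetum and anther on day 8 could be a source of such RNA, but its source and how many nuclei made it were not tested.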
